A study of Mus musculus with 2 samples.

How the data were processed

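The data were ATAC-seq peak lists from 2 libraries of mouse T cells, both in 1 group. The labels number them as biological replicates 1 and 2 and give each its own sample record but the same donor record, so whether they came from different animals is not known. Each library's file held peaks in the narrowPeak format on the mm10 build, per the labels and the deposited notes, called on that library alone and not on pooled reads. The aligner, the peak caller, their versions and the threshold were not given in the sources used here. Peak names in the deposited files contain the words ASTARR.insert, masked, dedup and sorted, which no source used here explains, so the kind of library that was sequenced rests on the labels alone. No step of shifting reads for the transposase could be checked, because the reads and signal tracks were not analysed here. A shift of a few bases would move summits by far less than the windows used.

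The authors' score in the fifth column is 10 times the −log10 q, rounded down and limited at 1000, in 99.999% of peaks. The deposited signal value in the seventh column is a ratio: it was read as fold enrichment over the caller's local background, from its values, since no source states it. The authors' −log10 p and −log10 q of each peak were taken as deposited, and the smallest −log10 q was 1.02 in replicate 1 and 1.01 in replicate 2. All are the caller's own values for that library, with no scaling between libraries stated. They were used to rank, filter and describe peaks. Depth per library is unknown, so a region missing from a list cannot be told from one below the threshold.

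Peaks on chromosomes 1 to 19, X and Y were kept (78016 and 74653). The 88 and 80 peaks on other sequences were left out. No peaks overlapped or touched within a library, so each was 1 region. A region was shared if it overlapped a region of the other library by at least 1 bp. Chance overlap came from 100 circular shifts of replicate 2 within each chromosome. For counts of shared regions, overlapping regions of both libraries were merged, and a merged region took the strongest summit.

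Genes and transcription starts were the 21853 protein-coding genes and 54361 starts of GENCODE mouse release 21, which has the coordinates of mm10, and sequence was taken from the same assembly. A summit within 1000 bp of any such start was a promoter. Other summits were assigned to exon, intron or intergenic, in that order. A gene's promoter was accessible if both libraries had a region there. Its distal regions were the shared non-promoter regions in the gene body and 20 kb on each side, so neighbouring genes can share a region.

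The 22 gene lists, the 26 consensus sequences, the tests, their alternatives and the rule for named genes were fixed before the data were examined. Of 314 different genes in the lists, 313 were matched, and 1, Clec7a, was not among the protein-coding genes of the annotation. Some genes are in more than 1 list. The rule named 25 of the genes described in any case, with a few fixed items not reported here, and, from each list, the 2 members with the strongest promoter, the 2 with the most distal regions and up to 2 with no region. It also named the 5 strongest shared regions and the 3 strongest of each library alone. That gave 111 genes, of which a part is described. The lists were not used to assign the cells to a subset.

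Promoter lists were compared with all other protein-coding genes by two-sided Fisher's exact test. Distal counts were compared, as the list's median, with 10000 random lists of the same size matched on decile of locus length, two-sided. Consensus matches on either strand in the 100 bp around the summit were divided by the mean of matches in 2 windows centred 500 bp to each side. A count of 0.5 was added to both before the division. The ratio was compared with 20 letter shuffles of the sequence, one-sided. Single-library and shared regions were compared by two-sided Fisher's exact test. P-values were adjusted by Benjamini-Hochberg over the lists or sequences, with a threshold of 0.05. No adjustment was made over the shuffle tests. All p-values describe genes or regions in these libraries, and no test between conditions or animals was possible with 1 group of 2 libraries. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. Where values are given as mean ± SD, n is the 2 libraries.

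The alternatives were a peak threshold of −log10 q of at least 5, the 50000 strongest regions per library, stricter overlap, other promoter distances, flanks, backgrounds and windows, and each library alone. The closing section gives their effect. The code was tested on simulated data. For a simulated second library, 69.9% of regions were made shared and the same share was recovered. Its shared regions were moved only slightly, so this checked the code alone. In 20 simulations of promoter lists, 99.5% of changed lists and 2.50% of unchanged lists were called. In 5 simulations of distal counts, 100% of changed and 0% of unchanged lists were called. All simulated lists held 20 genes, while the real lists held 9 to 28. The simulated share of accessible promoters in unchanged genes was below the real 65.0%. Power for the shorter real lists was therefore not shown. In 20000 simulated windows all 13 planted sequences and 0 of the 13 others passed all shuffles. Their bases were drawn at random with equal frequency in centres and flanks. How often other sequences pass in genomic sequence was therefore not shown.

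Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9.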

Results

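Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into DNA that is not wrapped tightly in nucleosomes, in mouse primary T cells of strain C57BL/6NJ. The data were 2 libraries of 1 group, numbered by the labels as biological replicates 1 and 2. The labels name the cells only as T cells and link to a protocol on differentiation of CD4+ T cells. The peak names in both files carry the words Th0, 72hrs and ASTARR.insert, which the labels do not explain, so the cells were not assigned to any T-cell subset. Whether the sequenced fragments came straight from the cells or were inserts of a library built from them is not known, and in the latter case peaks and signal would also carry the steps of building it. The deposited lists held 78104 peaks for replicate 1 and 74733 for replicate 2. The numbers of sequenced and aligned reads were not given in the sources used here, so the depth of each library is unknown.

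With 1 group, the design allowed a comparison of the 2 replicates and a description of which genes, regions and sequence motifs were accessible. In both libraries every one of the 28 T-cell core genes had an accessible region at its promoter, as had all 20 housekeeping and all 15 BAF chromatin remodelling genes. The loci of the T-cell core genes held a median of 9 distal regions, against 2.5 in random lists of their length. Of the other 9 lists of T-cell genes, 8 also held more distal regions than random lists, and Th1 did not pass. Neither difference passed for the T-cell core list with the 50000 strongest regions of each library. Promoters of hepatocyte and muscle genes were accessible less often than those of other genes, and the muscle result did not pass with replicate 1 alone. AP-1, CTCF, ETS and RUNX consensus sequences were concentrated at the summits of the regions that both libraries shared.

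On the standard chromosomes replicate 1 had 78016 regions and replicate 2 had 74653. They covered 58.1 and 56.2 Mb, which is 2.13% and 2.06% of the genome. The median region was 628 bp wide in replicate 1 and 638 bp in replicate 2. The authors' signal value, read as fold enrichment over local background, had a median of 6.50 in each library. The median −log10 q was 30.3 in replicate 1 and 23.9 in replicate 2.

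The first question was how far the replicates described the same accessible genome. Of the replicate 1 regions, 67468 (86.5%, exact binomial 95% interval 86.2 to 86.7) overlapped a replicate 2 region. Of the replicate 2 regions, 67382 (90.3%, 90.0 to 90.5) overlapped a replicate 1 region. When replicate 2 was shifted around each chromosome 100 times, the share of replicate 1 regions that overlapped averaged 4.38% and never exceeded 4.70%. The Jaccard index of covered bases was 0.753, against a mean of 0.0115 over the shifts. Merging the 2 libraries gave 84666 regions, of which 66847 (79.0%) were present in both, 10548 in replicate 1 alone and 7271 in replicate 2 alone.

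Sharing rose with the strength of a region. In the weakest decile of signal, 49.0% (47.9 to 50.1) of replicate 1 regions and 61.9% (60.8 to 63.0) of replicate 2 regions were found in the other library. From the ninth decile upward the shares were at least 99.9% in both directions. Across the 65721 regions that matched one to one, log2 signal had a Pearson r of 0.953 and a Spearman rho of 0.957. These are correlations across regions, which are not independent replicates, so no p-value is attached. The median ratio of replicate 1 to replicate 2 signal was 1.04, the SD of the log2 ratio was 0.23, and 37 regions differed by more than 2-fold. The −log10 p of the same regions was larger in replicate 1, with a median ratio of 1.36.

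**Figure D1:**
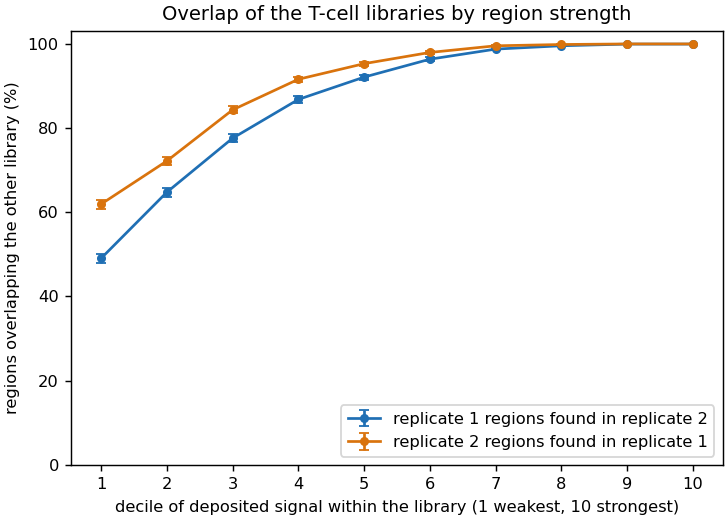
Share of regions overlapping the other library (y axis, percent) by decile of the deposited signal within each library (x axis, 1 weakest and 10 strongest), with exact binomial 95% intervals. Sharing climbs from 49.0% of replicate 1 and 61.9% of replicate 2 regions in the weakest decile to over 99.9% in the strongest.

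Promoters made up a far larger part of the accessible regions than of the genome. Of the 66847 shared regions, 14013 (20.96%, 20.7 to 21.3) had their summit within 1000 bp of a protein-coding transcription start, a class that covers 2.45% of the genome, which is an 8.57-fold excess (14.7-fold within 500 bp and 5.23-fold within 2000 bp). Introns held 42.6% of the regions and 40.0% of the genome, other exons 6.25% and 4.17%, and intergenic sequence 30.2% and 53.4%. Promoter regions were wider, with a median of 1274 bp against 685 bp in introns and 689 bp between genes. Their median signal was 10.5, against 6.39 in introns and 6.90 between genes. The 200 bp around promoter summits had a GC content of 64.2%, against 47.9% in introns. The promoter share was 18.7% in all regions of replicate 1 and 19.3% in those of replicate 2.

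Regions differed in density between chromosomes. Chromosome X held 1768 regions in replicate 1 and 1732 in replicate 2, which was 0.334 and 0.342 times the autosomal number per Mb. Chromosome 11 was the densest, with 47.1 and 44.8 regions per Mb against autosomal means of 30.95 and 29.6. Chromosome Y held 18 and 17 regions. Of 183 protein-coding genes on Y, 4 had a promoter region in both libraries: Kdm5d, Eif2s3y, Uty and Ddx3y, named after the data had been seen. Uty had a signal of 11.1 and 10.8 and Ddx3y 10.4 and 8.28, while Kdm5d was weakest at 3.97 and 2.97. Both libraries thus held Y-bearing cells, though the labels do not give the sex of the animals.

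The second question was which genes had accessible promoters. Of 21853 protein-coding genes, 14204 (65.0%) had a region within 1000 bp of a transcription start in both libraries, 386 in a single library and 7263 (33.2%) in neither. Among 25 genes fixed for individual description, 21 had a promoter region in both libraries and 4 had none in either. The 4 without one were Alb, which encodes serum albumin, the lysozyme gene Lyz2 of myeloid cells, the interleukin gene Il17a and the coreceptor gene Cd8a.

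**Figure D2:**
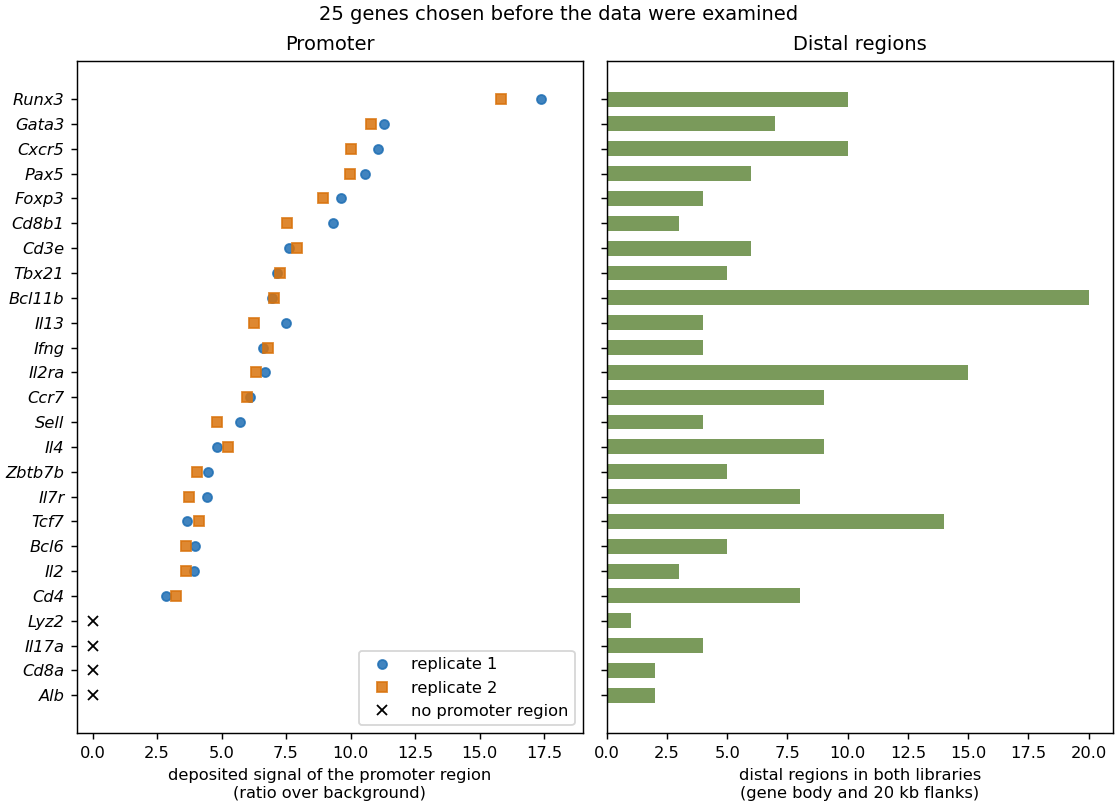
Deposited signal of the strongest promoter region in replicate 1 (circles) and replicate 2 (squares), and number of distal regions present in both libraries (bars), for 25 genes fixed for individual description; crosses mark the 4 genes with no promoter region. Runx3 has the highest promoter signal, 17.4 and 15.8, and Bcl11b the most distal regions, 20.

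Cd4 and Zbtb7b of the helper lineage had accessible promoters, and of the CD8 coreceptor pair only Cd8b1 did. The promoter signal of Cd4 was low, at 3.04 ± 0.284 (SD, n = 2), in a region on chromosome 6 at 124887980 to 124888717 in replicate 1. That of Zbtb7b, which encodes the ThPOK factor of helper T cells, was 4.27 ± 0.287 (SD, n = 2). Cd8b1 had 8.43 ± 1.27 (SD, n = 2), while Cd8a, at 71373427 to 71379173 on chromosome 6, had no promoter region and 2 distal regions. Runx3, a factor needed by CD8 T cells and active in other lymphocytes, had 16.6 ± 1.10 (SD, n = 2). As a list, the CD4 and CD8 lineage genes did not stand apart, with 7 of 9 promoters accessible (Fisher's exact test, adjusted p = 0.585).

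Genes used by T cells in general had accessible promoters without exception in 4 lists. All 28 T-cell core genes did (Fisher's exact test, adjusted p = 0.000192), against 65.0% of other genes. Their strongest promoters were those of Fyb, an adaptor of the T-cell receptor pathway (12.7 ± 0.0541, SD, n = 2), and Themis, a regulator of thymocyte selection (11.5 ± 0.185, SD, n = 2). Cd3e, a chain of the T-cell receptor complex, had 7.77 ± 0.227 (SD, n = 2). All 18 naive and memory genes (exact adjusted p = 0.00303) and all 22 activation genes (exact adjusted p = 0.00103) were accessible. With the gene's 5' end alone, 26 of 28 T-cell core genes (exact adjusted p = 0.00219) and 21 of 22 activation genes (exact adjusted p = 0.00320) were. Ccr7, the lymph node homing receptor, had 6.05 ± 0.0666 and Il2ra, the inducible interleukin 2 receptor chain, had 6.51 ± 0.265 (SD, n = 2). All 11 genes of the list of exhaustion and inhibitory receptors were accessible (exact adjusted p = 0.0263), led by Entpd1 at 17.9 ± 0.420 and Havcr2 at 12.7 ± 1.08 (SD, n = 2). This result was lost with replicate 2 alone (exact adjusted p = 0.0501), replicate 1 alone (0.0560), a region in either library (0.0502), −log10 q of at least 5 (0.0981) and the gene's 5' end alone (0.326).

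Of the lists named for helper subsets, Th1 passed the test at promoters. All 16 of its genes were accessible (exact adjusted p = 0.00446), including Tbx21, which encodes the Th1 regulator T-bet, at 7.21 ± 0.0634 and Ifng, its cytokine, at 6.71 ± 0.141 (SD, n = 2). Cxcr6 had the strongest promoter of this list, at 19.2 ± 0.0269 (SD, n = 2). The others did not pass: Th2 with 14 of 16 (exact adjusted p = 0.111), Th17 with 11 of 16 (1.00), regulatory T cells with 15 of 17 (0.0983) and T follicular helper cells with 11 of 12 (0.111). Promoters of regulators of the Th2, regulatory and T follicular helper subsets were accessible all the same. Gata3 had 11.04 ± 0.333, Foxp3 9.29 ± 0.506 and Bcl6 3.80 ± 0.232 (SD, n = 2). Whether the subset lists differed from each other was not tested.

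Among lists of other cell types, hepatocyte and muscle genes were accessible less often than other genes. Of 14 hepatocyte genes 2 were accessible, Apoa1 and Apob (exact adjusted p = 0.00103), and of 14 muscle genes 4 were (adjusted p = 0.0232). The muscle result was lost with replicate 1 alone (exact adjusted p = 0.0560), a region in either library (0.0502) and the gene's 5' end alone (0.0580). Serpina1a, Ttr, Myh1 and Myh4 had no region at the promoter or in their locus. The lists of B cells (7 of 16, exact adjusted p = 0.164), myeloid cells (7 of 17, 0.111), dendritic cells (5 of 10, 0.409), erythroid cells and megakaryocytes (5 of 12, 0.175) and epithelium (6 of 11, 0.585) did not pass. With the gene's 5' end alone, myeloid genes passed as lower (5 of 17, exact adjusted p = 0.0326). Nor, by the same exact test, did NK and innate lymphoid cells (8 of 12, 1.00), endothelium and fibroblasts (7 of 14, 0.346) and neurons (14 of 16, 0.111). Several genes of these lists had strong promoter regions in both libraries: Cr2 of B cells at 14.5 ± 1.88, Pax5 at 10.3 ± 0.420, Klf1 of erythroid cells at 15.2 ± 0.806 and Map2 of neurons at 12.6 ± 1.12 (SD, n = 2). All 20 housekeeping genes (exact adjusted p = 0.00126) and all 15 BAF chromatin remodelling genes (adjusted p = 0.00639) were accessible.

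These tests compare genes within 2 libraries, and genes are not replicates of an experiment. In a permutation test against random lists of the same promoter GC content, the exhaustion list (adjusted p = 0.0695) and the BAF list (0.141) no longer passed and the T follicular helper list did (0.0176). With the 50000 strongest regions of each library, 3 lists passed, hepatocyte and muscle lower and BAF higher. T-cell core promoters then fell to 18 of 28 (64.3% against 58.8% of other genes, exact adjusted p = 0.735) and activation promoters to 12 of 22.

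**Figure D3:**
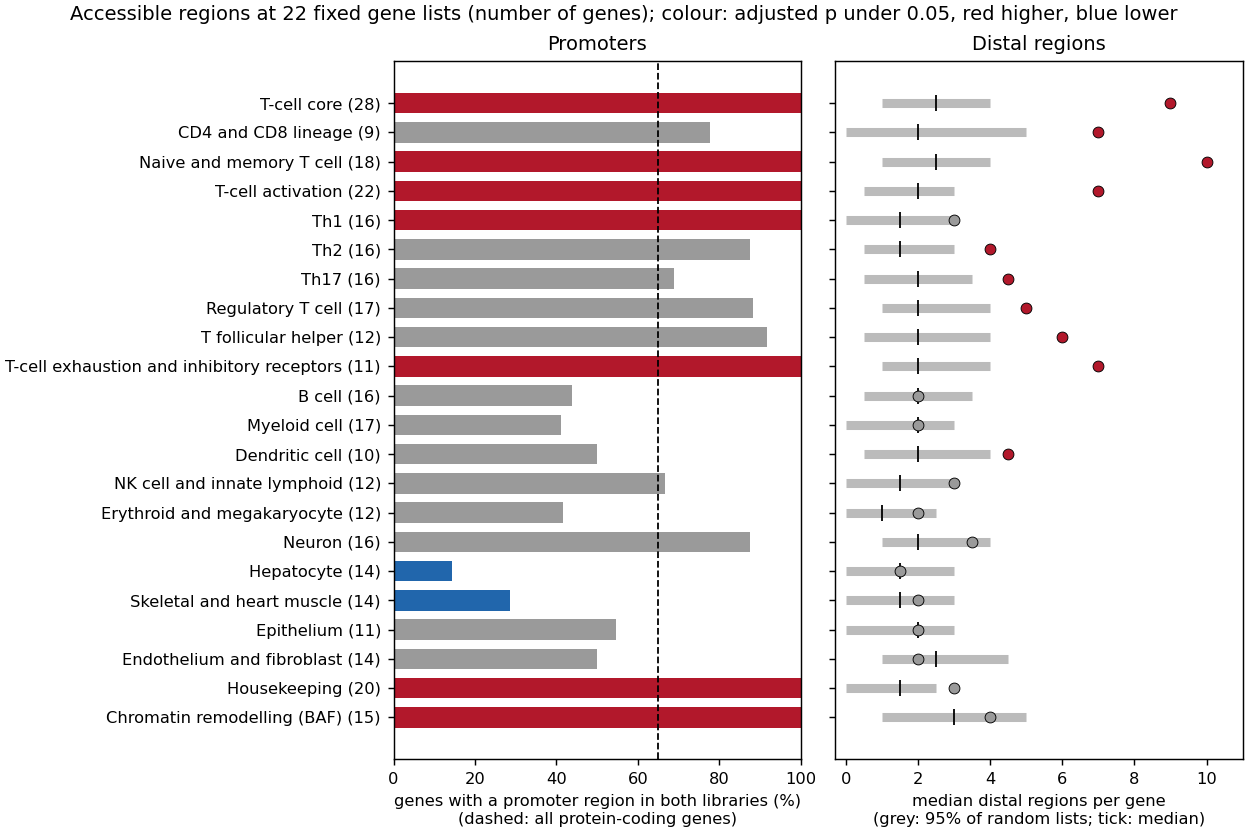
Left, percent of each fixed list's genes with a promoter region in both libraries (bars; dashed line, all protein-coding genes, 65.0%); right, median number of distal regions per gene (circles) over the central 95% (grey) and median (tick) of 10000 random lists matched on locus length. Colour marks an adjusted p under 0.05, red higher and blue lower; the T-cell core list stands at 100% of promoters and 9 distal regions.

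T-cell gene loci also held many accessible regions away from promoters. The median T-cell core gene had 9 non-promoter regions in its body and 20 kb flanks, against 2.5 in random lists matched on locus length (adjusted p = 0.0011, permutation test of 10000 lists, the smallest p they can give before adjustment being 0.0002). Naive and memory genes had a median of 10 against 2.5 and activation genes 7 against 2 (permutation adjusted p = 0.0011 each). Exhaustion and inhibitory receptor genes had 7 against 2 (permutation adjusted p = 0.0011), T follicular helper genes 6 against 2 (0.00176) and CD4 and CD8 lineage genes 7 against 2 (0.00733). Regulatory T-cell genes had 5 against 2, Th17 genes 4.5 against 2 and Th2 genes 4 against 1.5 (permutation adjusted p = 0.00978 each). Dendritic cell genes also had more, 4.5 against 2 (permutation adjusted p = 0.0352), led by Ccr9 with 12, a homing receptor that lymphocytes use too, and Flt3 with 8. The dendritic result was lost with replicate 2 alone (permutation adjusted p = 0.0785), replicate 1 alone (0.0608), −log10 q of at least 5 (0.152) and 50 kb flanks (0.0840). Random genes were drawn independently, while genes of a list can be neighbours that count the same regions. The permutation p-values of the distal lists may therefore be too small.

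Single loci held many distal regions. Foxp1, a factor of naive T cells, had 71 in a locus of 637 kb on chromosome 6, and Bach2, which restrains effector differentiation, had 50 in 387 kb on chromosome 4. Rora of the Th17 list had 40, Tox of the CD4 and CD8 lineage list 30, Prkcq 22, Bcl11b 20, Nrp1 20 and Stat4 18. Genes of other lists reached such numbers too: Arid1b of the BAF list had 34, Ebf1 of the B-cell list 20, Arid2 of the BAF list 15 and Pecam1 of the endothelial list 13. Tcf7, which encodes the TCF1 factor of naive and memory T cells, had 14 in 70.6 kb, where the median gene of its length class had 2. Il2ra had 15 in 90.4 kb, Cd4 8 and Il7r 8. The cytokine genes Il4, Il13, Ifng and Il17a had 9, 4, 4 and 4, and Il2 had 3. Of the 25 genes fixed for description, 23 had more distal regions than the median gene of their length class.

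Loci of the other lists did not pass the threshold against random ones: Th1 genes with 3 against 1.5 (permutation adjusted p = 0.175), NK and innate lymphoid genes with 3 against 1.5 (0.150), housekeeping genes with 3 against 1.5 (0.0640), BAF genes with 4 against 3 (0.613) and neuron genes with 3.5 against 2 (0.396). B-cell genes had 2 against 2 (1.00), myeloid genes 2 against 2 (1.00), erythroid and megakaryocyte genes 2 against 1 (0.614) and hepatocyte genes 1.5 against 1.5 (1.00). Muscle genes had 2 against 1.5 (0.987), epithelial genes 2 against 2 (1.00) and endothelial and fibroblast genes 2 against 2.5 (0.987). With gene bodies alone, 5 of the 10 lists passed, and with the 50000 strongest regions 4 did: naive and memory, activation, Th2 and Th17. The T-cell core list then had a median of 2 against 1 (permutation adjusted p = 1.00). Th1 passed with 50 kb flanks (permutation adjusted p = 0.00770) and with replicate 2 alone (0.00754). NK and innate lymphoid genes passed in the same settings (permutation adjusted p = 0.0240 and 0.0220), and housekeeping genes with replicate 2 alone (0.0198) and replicate 1 alone (0.0321).

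The third question was which transcription factor binding sequences lay at the accessible sites. Of 26 consensus sequences, 14 were concentrated in the central 100 bp of the shared regions beyond all 20 letter shuffles of the same sequence (p = 0.0476 each, the smallest that 20 shuffles allow, permutation test), where chance would give 1.24. The AP-1 site TGASTCA, bound by Fos, Jun and BATF proteins that act after T-cell receptor signalling, was in 15.4% of summits and 1.56% of flanks, a ratio of 9.92. The CTCF site, bound by the insulator protein CTCF, was in 4.52% of summits with a ratio of 64.98. ETS sites had a ratio of 6.02 and RUNX sites, bound by Runx1 and Runx3, a ratio of 3.28. Composite AP-1 and IRF sites, which BATF and IRF4 can bind together, had ratios of 16.6 with 4 bp spacing and 16.9 when adjacent, though in 0.310% and 0.479% of regions. Both contain the whole AP-1 site, which letter shuffles break up. Passing the shuffles therefore does not show that the IRF part adds to AP-1, and the 14 are not all separate results.

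The other sequences past all shuffles were NRF1 (ratio 13.1), NF-kB (3.40), SP (3.33), PU.1 (2.81), STAT (2.08), IRF (1.70), MEF2 (1.31) and KLF (1.201). The SP sequence is all G but for a single base, so it has few distinct letter orders. Its shuffles repeat, and its shuffle p-value is smaller than they can bear out. Those not past all shuffles included the T-box site of Tbx21 (1.14), the GATA site of Gata3 (0.823), the TCF/LEF site (1.24) and the NFAT site (0.976). NFY (1.97), YY1 (1.37), CEBP (0.960), HNF4 (0.760), the B-cell factor EBF1 (0.854) and both E-boxes (1.40 for E2A and 1.06 for ZEB) did not pass either. NF-kB no longer passed with a 200 bp window, random genomic windows or the 50000 strongest regions, and NRF1 no longer passed with distal regions alone or random windows. NFY passed all shuffles with the 50000 strongest regions (ratio 2.32).

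Promoters and distal regions carried different sequences. AP-1 was in 18.8% of distal and 2.85% of promoter summits, CTCF in 5.47% and 0.942%, and RUNX in 4.11% and 0.799% (Fisher's exact test, adjusted p = 2.6e-155 for CTCF and 1.3e-107 for RUNX, below the range of double precision for AP-1). Of the 26 sequences, 17 were more frequent in distal regions, 5 in promoters and 4 did not differ past the threshold. The 5 promoter sequences were SP (7.34% of promoter and 0.649% of distal summits), NRF1 (0.628% and 0.0303%), NFY (12.4% and 3.84%), YY1 (1.73% and 0.636%) and KLF (4.43% and 3.17%). A consensus match is a sequence property and does not show that a factor was bound.

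**Figure D4:**
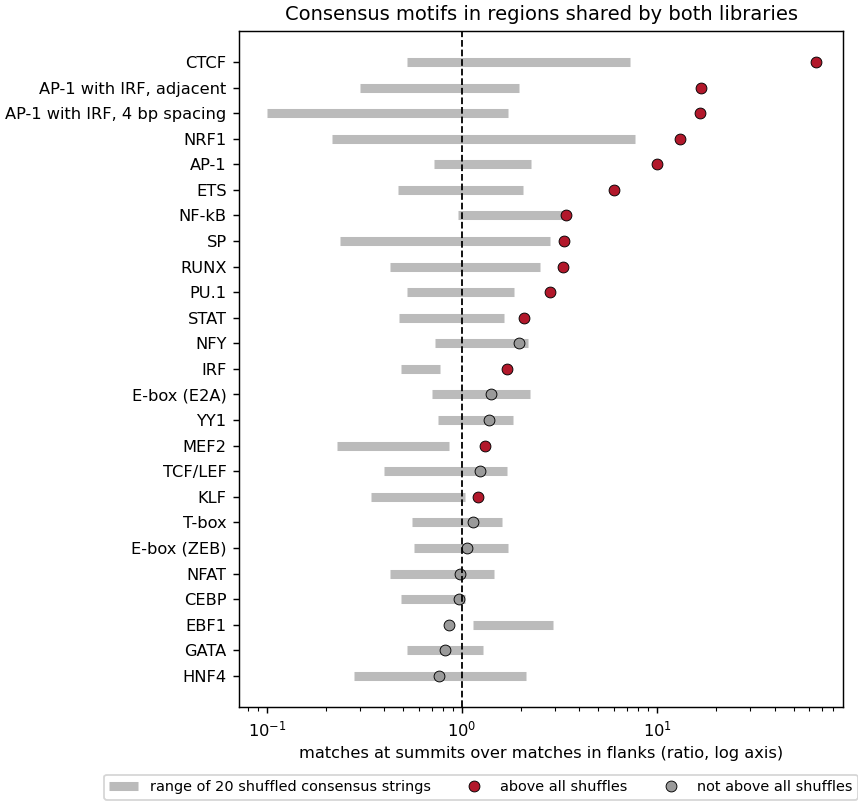
Ratio of consensus matches in the central 100 bp of the 66847 shared regions to matches in windows 500 bp to each side (x axis, log scale), for 25 of the 26 consensus sequences. Circles are the observed ratios, red where above all 20 letter shuffles of the sequence, and grey bars the range of the shuffles; CTCF is highest at 64.98.

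The last question was what kind of region the replicates did not share. The 17819 regions of a single library were mostly weak, narrow and distal. Their median signal was 3.31 and median width 300 bp, against 7.67 and 776 bp in shared regions. The width of a shared region spans the merged regions of both libraries, so it is at least that of either alone. Their median −log10 q was 5.17 against 40.2. Promoters were 4.27% of them against 20.96% of shared regions (Fisher's exact test, p below the range of double precision). Their summits carried fewer promoter sequences: SP was in 0.354% against 2.05% (exact adjusted p = 2.6e-72), NFY in 3.65% against 5.63% (6.5e-27) and NRF1 in 0.0168% against 0.156% (3.8e-07). CTCF fell from 4.52% of shared to 3.17% of single-library regions (exact adjusted p = 1.7e-15), and stayed lower with −log10 q of at least 5 (4.21% against 4.76%, 0.0282) and with width matching (3.17% against 5.73%, 0.0397). Among the 50000 strongest regions of each library it was higher in single-library ones (6.00% against 5.14%, exact adjusted p = 0.00767). With −log10 q of at least 5 and with the 50000 strongest, each list was cut before the comparison. A region then counted as single-library if the other library's cut list lacked it, even where its full list held it. These values can therefore also cover regions listed in both libraries.

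AP-1 was nearly as frequent in single-library regions, at 14.6% against 15.4% (exact adjusted p = 0.0221). Its direction turned when both lists were first cut at −log10 q of at least 5, at 17.5% against 15.8% (exact adjusted p = 3.5e-05). With regions that had none of the other library within 1000 bp, the results for AP-1 (15.41% against 15.45%, exact adjusted p = 0.911), RUNX (0.146), PU.1 (0.0667) and YY1 (0.0544) were lost, which left 8 lower. In all, 12 of the 26 sequences were less frequent in single-library regions, 1 (the ZEB E-box, 8.61% against 7.88%, exact adjusted p = 0.00533) was more frequent and 13 did not differ past the threshold. The ZEB result was lost with −log10 q of at least 5 (exact adjusted p = 0.114) and the 50000 strongest regions (0.148), and its ratio turned to 0.923 with width matching. Matching on width left 611 shared regions, among which promoters were 6.87% (Fisher's exact test, p = 0.00334). Against so few regions SP (0.354% against 0.818%) and NFY (3.65% against 5.07%) stayed lower without passing (exact adjusted p = 0.450 each), and NRF1 could not be compared, with 0 shared matches.

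Some unshared regions were strong. In replicate 1 the strongest was on chromosome 1 at 171074300 to 171074684, intergenic and 9.54 kb upstream of Fcgr3, with a signal of 17.0. The next were on chromosome 1 at 189927579 to 189928206, upstream of Smyd2 (14.7), and in an intron on chromosome 4 at 10896844 to 10897164 (14.4). In replicate 2 they were in introns on chromosome 9 at 119430275 to 119430606 (13.7, nearest start Exog) and on chromosome 5 at 20470540 to 20470832 (11.5, nearest start Magi2), and between genes on chromosome 17 at 64375427 to 64375773 (10.8, nearest start Pja2).

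None of the 5 strongest shared regions was at a promoter, and 4 of them were narrower than 500 bp. The first lay in an intron on chromosome 1 at 100180105 to 100180425, with a signal of 38.5 in replicate 1 and 36.8 in replicate 2. The second lay in an exon on chromosome 9 at 123461798 to 123462184 (36.0 and 34.8). The others were in an intron on chromosome 12 at 78350869 to 78351174 (34.0 and 33.0) and between genes on chromosome 8 at 19784201 to 19785276 (31.7 and 29.9) and chromosome 3 at 5860341 to 5860821 (30.9 and 28.4). In 4 of these 5 regions more than 50% of the 31-base sequences occurred elsewhere in the assembly.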

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

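Peaks outside the standard chromosomes were not used in any comparison, and their number was above the 3 that a count of 0 allows. On unplaced and unlocalized scaffolds there were 86 peaks in replicate 1, on 17 scaffolds, and 78 in replicate 2, on 16. Of these, 29 and 25 lay on the scaffold JH584304. Their median signal was 4.54 and 4.64, and the highest was 31.9 and 30.3. The mitochondrial sequence held 2 peaks in each library.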

How the results depend on the processing

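All alternatives here were fixed before the data were examined, and the cause of a change was not tested unless the setting itself gives it. Of 85 main results under an alternative, 49 stayed and 36 moved, by leaving their interval or SD or, for counts and ratios, by more than 1.5 times. Of the single lists, sequences and classes, 463 kept direction and call, 57 lost the call, 10 gained it, 37 turned direction and 14 shares moved. Overlap: replicate 1 regions found in replicate 2 were 87.3% with −log10 q of at least 5, 91.9% with the 50000 strongest, 80.9% with reciprocal overlap of 50% and 75.3% with summits within 100 bp; replicate 2 regions found in replicate 1 were 94.1%, 91.9%, 84.6% and 78.7%. The Jaccard index was 0.773 and 0.782 with the first 2 of these. Pearson r and Spearman rho were 0.952 and 0.953 with −log10 q of at least 5, 0.928 and 0.930 with the 50000 strongest, a narrower range of signal, 0.951 and 0.955 with mean signal, and 0.954 and 0.958 with reciprocal overlap. The promoter share was 22.1% with −log10 q of at least 5, 26.3% with the 50000 strongest, 19.02% within 500 bp, 24.1% within 2000 bp and 18.7% to 19.3% with 1 library left out. The Y chromosome density over autosomes was 0.00645 with −log10 q of at least 5, against 0.00630.

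Promoter lists higher were 1 with the 50000 strongest regions, and lists lower were 1 with a region in either library, and 1 with 1 library left out (replicate 2). Lists whose direction turned were, with −log10 q of at least 5, Th17 (62.5% accessible) and NK and innate lymphoid (58.3%). With the 50000 strongest they were CD4 and CD8 lineage (55.6%), activation (54.5%), Th17 (50%) and NK and innate lymphoid (41.7%). Within 500 bp they were Th17 (62.5%) and NK and innate lymphoid (58.3%), at the 5' end alone Th17 (56.2%), and with a region in either library epithelium (72.7%). Of these only activation had passed the test. Distal lists higher were 4 with the 50000 strongest and 5 with gene bodies alone. None of the distal lists that turned had passed: with the 50000 strongest, hepatocyte (median 1); with 50 kb flanks, erythroid (2.5), neuron (4.5) and hepatocyte (5); with gene bodies alone myeloid, NK and innate lymphoid, erythroid, epithelium and housekeeping (0 each); with matching on promoter accessibility, hepatocyte (1.5) and endothelium and fibroblast (2); without replicate 1, hepatocyte (2).

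Motif ratios that turned against the shuffle median, none past all shuffles before, were GATA with the 50000 strongest (0.722), YY1 with distal regions (0.949) and random windows (1.00), the E2A E-box with distal regions (1.45) and HNF4 without replicate 2 (0.631 to 0.770 with 1 library left out). In single-library regions the sequences lower and higher numbered 6 and 2 with −log10 q of at least 5, 3 and 5 with the 50000 strongest, and 1 and 0 with width matching, which leaves 611 shared regions. With the first 2 of these settings, a single-library region was missing from the other library's cut list, though its full list may hold it. Among the 13 sequences that had passed, the ratio of single-library to shared frequency turned for AP-1 with −log10 q of at least 5 (1.10), for CTCF (1.17), ETS (1.01), RUNX (1.15), AP-1 (1.16) and IRF (1.00) with the 50000 strongest, and for ETS (1.54), NF-kB (1.65), KLF (1.49) and the ZEB E-box (0.923) with width matching. Among the 13 that had not passed, left out of the 37 above, it turned in 10 cases, 0 of them past the threshold, among them AP-1 with adjacent IRF (1.39), STAT (1.06) and MEF2 (1.21) with the 50000 strongest. NRF1 gave no ratio with width matching, because no shared region held it. No paired analysis was possible because the design has 1 group. Without known depth, an absent region cannot be told from one below the caller's threshold.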

Other observations

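Everything in this part was chosen after the data had been seen, except that 4 tests were fixed before their own values were computed: the motif and copy tests of the strong single-library regions and of the strongest shared regions. Some loci held dense distal regions. Per 100 kb of gene body and flanks, the densest were Spn, which encodes the sialoglycoprotein CD43 (21.9 shared distal regions), the stress response gene Ddit4 (21.3), the adaptor gene Grap (20.2), Tcf7 (19.8), the lymphoid factor gene Ikzf1 (19.5), the transcription elongation gene Supt4a (19.5), the GTPase gene Gimap6 (19.3), Il6ra (19.1) and Irf4 (19.05). Of these, Tcf7, Il6ra and Irf4 were in the fixed lists. Whether immune genes are over-represented in this ranking was not tested. Inpp4b, a phosphoinositide phosphatase gene, had 68 distal regions in 825 kb.

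Gene families fell far apart at promoters, where 65.0% of all protein-coding genes were accessible. Membership of the groups was not checked against a curated list, so a group can hold other genes or miss members. The IRF group of 12 genes is larger than the family of IRF factors. All 12 genes of that group and all 7 of the STAT group were accessible in both libraries. So were 19 of 20 genes grouped as TNF receptor superfamily (95%, exact 95% interval 75.1 to 99.9) and 31 of 41 grouped as interleukin receptors (75.6%, 59.7 to 87.6). So were 33 of 39 Hox genes (84.6%, 69.5 to 94.1), which pattern the embryonic body axis. Other immune families lay lower: 16 of 37 chemokine ligands (43.2%, 27.1 to 60.5), 6 of 15 killer lectin-like receptors outside the Ly49 group, 2 of 10 granzymes and 1 of 13 type I interferon genes of the Ifna group. The shares were 19 of 1134 olfactory receptors (1.68%, 1.01 to 2.60), 1 of 329 vomeronasal receptors and 0 of 11 Ly49 receptors of NK cells. The antigen receptor loci differed as well. The T-cell receptor beta locus, 667 kb on chromosome 6 at 40891229 to 41558452, held 32 shared regions, 4.80 per 100 kb (exact Poisson 95% interval 3.28 to 6.77) against 2.45 over the genome. The T-cell receptor alpha and delta locus had 25 shared regions, 1.39 per 100 kb (0.901 to 2.05). The 101 kb around its constant genes held 14, but that window reaches past the end of the locus, so these need not all be among the 25. The immunoglobulin heavy chain locus had 1.09 (0.737 to 1.56), the kappa locus 0.0946 (0.0195 to 0.276), and the lambda and T-cell receptor gamma loci had 0 regions (0 to 1.85 and 0 to 2.80), so the short gamma locus is not shown to differ from the genome. Family and locus differences were not tested.

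Replicate 1 had more regions and larger −log10 p values than replicate 2 at nearly the same signal. Stronger enrichment in replicate 1 is argued against by the median signal ratio of 1.04 at shared regions, where the −log10 p ratio was 1.36. A deeper library of replicate 1 is a candidate explanation: in about 29.8% of regions of each library the signal was a whole multiple (within 0.01) of a fixed step. If that signal is coverage plus 1 over background plus 1, an assumption about the caller, the step gives a background coverage of 5.04 in replicate 1 and 3.71 in replicate 2, a ratio of 1.36. The read numbers that would settle this were not analysed here, and no biological explanation was tested.

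A signal of at least 8 with no region of the other library within 1000 bp occurred in 155 regions, 114 in replicate 1 and 41 in replicate 2, with a median −log10 q of 32.3. Scatter around the caller's threshold was not settled. There were 31667 shared regions with a signal of at least 8 in either library. In the other library 37 of them had under 5, 5 under 4 and 0 under 3, although 8196 and 6877 regions under 3 were listed. Such drops were thus rare among regions listed in both libraries. A region that fell below the threshold in 1 library is not among them, so scatter remains possible for the 155. Copied sequence is argued against by a median of 0% of 31-base sequences with another copy in the assembly. Fragments amplified at sites without a regulatory element are argued against by AP-1, CTCF, ETS or RUNX consensus matches in 65 of them (41.9%, 34.1 to 50.1), against 28.6% in shared regions of the same signal; promoters, where 3 of these sequences are rarer, were 1.94% and 18.2%, and without promoters the shares were 41.4% (33.5 to 49.7) and 32.9%. Amplified fragments at weak but true sites, an undocumented filter of the authors and a difference between the cell samples may each remain, and none was tested.

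The 100 strongest shared regions may in part collect reads from repeated sequence. In the median such region 14.2% of 31-base sequences occurred elsewhere in the assembly, against 0% in 2000 random shared regions, and in 20 of the 100 more than 50% did. They were unlike the other shared regions in class, with 41 promoters of the 100 (31.3 to 51.3) against 20.96%. Whether they are regulatory elements as often as the others cannot be told apart: 23.0% (15.2 to 32.5) carried an AP-1, CTCF, ETS or RUNX consensus against 24.2% of all shared regions, an interval too wide to decide. AP-1, CTCF and RUNX were also rarer at promoters, and these shares were not compared without promoters. No biological explanation was tested.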
